A study of Mus musculus with 4 samples.

How the data were processed

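The 4 libraries came from primary mouse microglia: 2 untreated controls and 2 treated with LPS at 10 ng/ml for 4 h, grouped by the treatment given in the labels. Per the labels' protocols, microglia were shaken off mixed glial cultures and plated again, ribosomal RNA was removed, and directional libraries were sequenced as paired ends on an Illumina HiSeq instrument. No sort or gate for microglia is described. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.33, TopHat2 2.0.10, Cufflinks 2.2.1, HTSeq 0.6.1 and the mouse genome build mm10. The role of each tool, the counting mode, the strand setting and the annotation are not given in the sources used here. Overlapping genes, antisense partners and near-identical paralogs may therefore share or lose reads in ways that cannot be traced.

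The authors deposited 1 table of whole-number counts for 32915 RefSeq transcript accessions in 4 columns, 1 per library. The table is called normalized by its name. The values bear no clear mark of rescaling, though the checks are limited. Between 4 and 80 each whole number occurs in each library, where scaling up and rounding would mostly leave gaps. Scaling down leaves none, and differing totals do not exclude a normalization. A search over 280 factors below 1 raised the log-likelihood of the value pattern by at most 3.74 (LPS replicate 1). Median log2 ratios to the mean of libraries were -0.208 and 0.202 for control and 0.027 and -0.015 for LPS. Scaling by median ratios would have narrowed these. A division by exactly 2 cannot be ruled out from the values. They were treated as counts, so the test planned for counts was the main one, and the test planned for normalized values, limma-trend on log2(count + 1), was run as an alternative chosen after the data were seen. Column names matched the sample labels, and 0 columns were left unused.

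Accessions were matched to gene symbols with a RefSeq gene table of assembly GRCm38.p6 (32487 accessions) and the metadata of a GENCODE release (187); 241 matched neither and were kept under their own identifier. Counts were summed over the accessions of a gene, giving 24148 genes, of which 2796 had no count. Of the named genes, 4801 had more than 1 accession. These had lower counts than genes with 1 accession, as the closing section describes, and their levels are uncertain. A single non-coding accession that the reference does not name held 24.8% and 23.7% of counts in control replicates 1 and 2 and 20.0% and 24.4% in LPS replicates 1 and 2, and Lars2 held 13.0%, 5.02%, 10.5% and 6.07%. All accessions without a reference name held 24.9%, 23.8%, 20.1% and 24.6%. The 10 most abundant genes held 48.4%, 40.6%, 39.4% and 39.5%.

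Genes with a mean count of at least 10 over the 4 libraries were tested (9548 genes). LPS was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM scaling, all 4 libraries in 1 fit, no covariate, and Benjamini-Hochberg adjustment at 0.05. TMM factors were 1.05 and 1.28 for the control and 0.820 and 0.906 for the LPS libraries. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.283. Replicates differed by more than sampling noise (chi-square per degree of freedom 33.1 in control and 26.4 in LPS), so none was treated as a repeat deposit of another; this does not show that they are independent samples. A value printed for a group with 1 to 3 counts, also with 1 library left out, is a ratio from counts with its 95% interval (Clopper-Pearson), and with 0 counts a lower bound from 3 counts over the group.

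In total 31 gene lists were fixed before the data were examined, as were the comparison, the filter and the rule for named genes. The lists covered pro-inflammatory cytokines, chemokines, type I interferon response, NF-kB, immediate-early factors, negative feedback, Toll-like receptors, homeostatic and disease-associated microglia genes, antigen presentation, complement, inflammasome, eicosanoid and nitric oxide enzymes, NRF2 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, LXR targets, lysosome, alternative activation, cell cycle, heat shock, endoplasmic reticulum stress, and markers of astrocytes, oligodendrocytes, neurons, fibroblasts, endothelium, border macrophages, monocytes and neutrophils, and lymphocytes. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. With an estimated correlation, the camera p also rests on the few residual degrees of freedom of 4 libraries, so it rarely reaches a call. Counts over a list refer to tested members. Members under the minimum count, often genes with more than 1 accession, were not tested. Named genes were the 10 called genes with the largest increase and the 10 with the largest decrease whose LPS libraries lay on 1 side of both controls (predicted genes, RIKEN names and pseudogenes counted but not named), 15 genes fixed in advance, and up to 4 called members of each list or, with no call, its 2 most abundant members. Of 99 genes under this rule, 97 were tested, and results for some of them are not reported here. Coordinates are those of GRCm38, the assembly that mm10 also denotes, as whole genes.

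The fit was tested on simulated counts drawn for the 9548 genes from the means and library sizes of these samples. At log2 changes of 1, 2, 3 and 5 (50 genes each) it recovered 4%, 64%, 94% and 100%, 4.38% of its calls were false, and 2.5% of 200 unchanged lists had a camera p under 0.05. Genes were drawn independently of each other and the unchanged lists at random. These shares therefore do not cover correlated genes or levels shared by libraries of the same number. Alternatives were the replicate number as a block, pseudocounts of 0.5 and 8 and quantile normalization in limma, limma without a mean-variance trend, no filter, a minimum mean of 50, filterByExpr, DESeq-type size factors, DESeq2 1.42.0, and each library left out in turn. Added after the data were seen were total-count scaling, limma-trend, 1 test per accession, genes with 1 accession only, and a run without the unnamed accession and Lars2. The limma fits other than quantile normalization used log2 counts without library-size or TMM scaling. A call lost in them cannot be told apart from an effect of uncorrected depth. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.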

Results

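Gene expression was measured by RNA sequencing in primary mouse microglia, the resident macrophages of the brain, grown from mixed glial cultures and collected by shaking. The cells received no treatment (control, 2 libraries) or lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is sensed through the receptor Tlr4, at 10 ng/ml for 4 h (2 libraries). The count tables held 3617176 and 4080568 counts in control replicates 1 and 2 and 5095630 and 4592474 counts in LPS replicates 1 and 2. A count above 0 was found for 18394 and 19597 genes in the control libraries and for 17543 and 17442 genes in the LPS libraries. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Levels are given as CPM (counts scaled to library size after TMM normalization) as mean ± SD with n = 2 libraries per group, and log2 fold changes of LPS over control carry their standard error. Where a call was lost when 1 library was left out, the value without it is given, with the range of adjusted p over the other settings without a replicate block. The limma settings other than quantile normalization left differences in depth uncorrected.

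The comparison asked how 4 h of LPS changed the transcriptome of these microglia. Antiviral, chemokine and cytokine genes showed the steepest increases. Rsad2, an interferon-induced antiviral enzyme also known as viperin, went from 9.47 ± 2.71 CPM in control to 9403 ± 880.5 CPM in LPS (n = 2 each), 998-fold higher (log2 fold change 9.96 ± 0.36). Il6, which encodes a pyrogenic cytokine, went from 1.30 ± 0.347 to 993 ± 179 CPM, 729-fold higher (9.51 ± 0.34). Cxcr4, the receptor of the chemokine Cxcl12, went the other way, from 513 ± 34.0 to 50.3 ± 4.77 CPM, 10.2-fold lower (-3.35 ± 0.21). Their edgeR adjusted p-values were 2.9e-04, 2.9e-04 and 8.7e-04.

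Of 9548 genes tested with edgeR's quasi-likelihood test, 625 were higher and 171 lower in LPS at an adjusted p under 0.05. At least 2-fold changes were held by 607 of the higher and 168 of the lower genes. The median fold was 5.50 among genes called higher and 3.46 (control over LPS) among genes called lower, and 87 genes were at least 32-fold higher while 20 were at least 8-fold lower. For all 796 called genes both LPS libraries lay on 1 side of both control libraries. The same libraries gave the calls, so this is no separate evidence. Among genes that were not called 4031 did so too, where chance alone gives 33.3% of genes if libraries are exchangeable. Higher genes made up 78.5% of the calls; this share was 61.9% after quantile normalization and 49.0% with total-count scaling, which shifted the median log2 fold change of all genes from -0.05 to -0.48. The numbers of calls fell to 335 higher and 33 lower without LPS replicate 1 and to 435 higher and 39 lower without LPS replicate 2, and the number of lower genes was 260 without control replicate 2. In simulated data with 50 changed genes at each size, the test recovered 4% of genes changed by a log2 of 1, 64% at 2, 94% at 3 and 100% at 5, so that a gene without a call may still have changed by 2-fold or more.

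The 10 genes with the largest fitted increases encode chemokines, cytokines, interferon-induced proteins and the enzyme Acod1. The rank of Csf3 rests on a fitted value over 0 control counts, and its bound of 77.6-fold would not place it among them. Cxcl10 (chromosome 5, 92346638 to 92348889, GRCm38), a chemokine that attracts activated T cells, had 1 and 0 counts in control and 3150 and 4064 counts in LPS. Its ratio from counts was 7772, with a 95% counting interval of 1394 to 307000, and its adjusted p was 3.7e-04. Rsad2 (chromosome 12, 26442743 to 26456452) and Cmpk2 (chromosome 12, 26469117 to 26479837), a nucleotide kinase gene beside it, had log2 fold changes of 9.96 ± 0.36 and 9.65 ± 0.45. Csf3 (chromosome 11, 98700183 to 98703631), which encodes the granulocyte growth factor G-CSF, had 0 counts in both control libraries and 84 and 132 counts in LPS, at least 77.6-fold higher when 3 counts are allowed over the control group (44.5-fold without control replicate 1 and 32.2-fold without control replicate 2). Gbp5 (chromosome 3, 142496934 to 142522344), an interferon-inducible GTPase, was 881-fold higher (9.78 ± 0.37), and Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine for T cells and monocytes, was 821-fold higher (9.68 ± 0.36). Ifit1, which binds foreign RNA, was 731-fold higher (9.51 ± 0.48), and the cytokine gene Il1a rose by a log2 of 9.40 ± 0.35. Acod1 (chromosome 14, 103047012 to 103056573), the enzyme that makes itaconate, went from 18.1 ± 6.19 to 10732 ± 1722 CPM and was the most abundant of these transcripts in LPS. Without control replicate 2 the ratio from counts of Cxcl10 was 3223 (log2 11.65, interval 9.18 to 16.96). Without control replicate 1, which held its only control count, Cxcl10 was at least 1486-fold higher when 3 counts are allowed in the other control library, and the log2 fold change of Ifit1 was 10.22. Intervals and floors cover counting error only.

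Among pro-inflammatory cytokines, 12 of 14 tested genes rose over all genes tested, and 13 rose when adjusted over the list alone. Their median log2 fold change was 5.72, or 5.55 with Csf3 at its bound, and the set test camera called the list higher (adjusted p = 1.2e-38; adjusted p = 0.15 with an estimated correlation). Il1b, the precursor of a cytokine released after inflammasome cleavage, went from 20.4 ± 2.32 to 7272 ± 1323 CPM, 354-fold higher (adjusted p = 2.9e-04). Il27, a cytokine of myeloid cells that acts on T cells, rose by a log2 of 8.68 ± 0.44. Without control replicate 2 its control count was 1 and its log2 ratio from counts 9.49 (interval 7.01 to 14.80). Tnf rose by a log2 of 3.51 ± 0.57 on small counts, 4 and 2 in control and 29 and 38 in LPS (adjusted p = 0.020). It has 2 accessions in the count table, and reads shared between them may not have been counted. The call of Tnf was lost without control replicate 2 (2.87, adjusted p = 0.050), LPS replicate 1 (3.69, 0.052) or LPS replicate 2 (3.30, 0.073, range 0.0013 to 0.073), and its log2 ratio from counts was 4.37 (interval 2.46 to 7.45) without control replicate 1. The anti-inflammatory cytokine gene Il10 had 5, 6, 6 and 12 counts, under the minimum for testing.

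Of 18 chemokine genes, 16 rose, 16 also when adjusted over the list alone, with a median log2 fold change of 7.10 (camera adjusted p = 8.7e-56; adjusted p = 0.30 with an estimated correlation). The neutrophil attractants Cxcl1 and Cxcl2 rose by 9.20 ± 0.33 and 9.21 ± 0.79 on the log2 scale, and Cxcl2 by 8.44 without control replicate 2 and by 10.51 without control replicate 1.

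The type I interferon response held the highest share of called genes of all lists, with 25 of 26 tested genes higher over all genes tested and 26 when adjusted over the list alone (median log2 fold change 5.60; 5.75 within the libraries numbered 1 and 4.93 within those numbered 2). Camera gave an adjusted p of 3.3e-115, and an adjusted p of 0.20 with an estimated correlation. Rsad2, Gbp5, Cmpk2 and Ifit1 led this list. Ifi44, chosen after its values were seen, was the member without a call (5.15, adjusted p = 0.054), with 3 and 47 counts in control and 286 and 1254 in LPS. It was called when control replicate 1 (4.35, 0.0093), control replicate 2 (adjusted p = 0.0016; log2 ratio from counts 7.84, interval 6.29 to 10.12) or LPS replicate 1 (5.86, 0.031) was left out, and had an adjusted p of 2.6e-04 to 0.11 over the settings. In antigen presentation and costimulation, 8 of 11 genes rose, and 11 when adjusted over the list alone (median 2.40; camera adjusted p = 9.9e-12; adjusted p = 0.30 with an estimated correlation). Nlrc5, a transcriptional activator of MHC class I genes, rose by 4.11 ± 0.25, the immunoproteasome subunits Psmb9 and Psmb8 by 3.40 ± 0.36 and 2.85 ± 0.32, and the peptide transporter subunit Tap2 by 3.26 ± 0.62. Tap2 had values of 4.43 without control replicate 1 and 2.53 without control replicate 2, and its call was lost without LPS replicate 1 (2.87, adjusted p = 0.11, range 1.5e-06 to 0.11), a setting in which 5 genes of this list were called. In the antigen presentation list 9 members were under the count minimum, 6 of them with more than 1 accession. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 were among the 9. B2m, the light chain of MHC class I, was chosen after its values were seen, as the 1 called gene whose sign changed in any setting. It was called higher (1.03, adjusted p = 0.044), had a value of -0.19 after quantile normalization (0.43), and lost its call without control replicate 1 (1.01, 0.064), control replicate 2 (1.01, 0.063), LPS replicate 1 (0.82, 0.30) or LPS replicate 2 (1.22, 0.10, range 0.0028 to 0.43), in limma-trend (0.93, 0.13), in limma without a trend (0.93, 0.31) and with total-count scaling (0.59, 0.15).

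Genes of NF-kB subunits and inhibitors rose in 11 of 14 cases, also when adjusted over the list alone (median 2.90; camera adjusted p = 1.7e-17; adjusted p = 0.30 with an estimated correlation). Traf1, an adaptor of TNF receptors, rose by 6.95 ± 0.59, and the inhibitors of NF-kB Nfkbie and Nfkbia by 4.14 ± 0.35 and 3.48 ± 0.46. Tnfaip3, the ubiquitin-editing enzyme A20, rose by 4.10 ± 0.54, with 2 accessions and an uncertain level. Without control replicate 1 these values were 6.29 for Traf1 and 4.21 for Nfkbia, and the log2 ratio from counts of Tnfaip3 was 4.96 (interval 3.07 to 8.03). Without control replicate 2 that of Traf1 was 8.74 (6.89 to 11.79) and the value of Tnfaip3 was 3.46. Negative feedback regulators rose in 7 of 13 cases and in 10 when adjusted over the list alone (median 2.62; camera adjusted p = 1.4e-12; adjusted p = 0.30 with an estimated correlation). The phosphatase Dusp2 (5.20 ± 0.37), the cytokine signalling inhibitor Socs3 (4.51 ± 0.37), Cd274, the ligand PD-L1 (4.33 ± 0.27), and the kinase-like inhibitor Irak3 (4.07 ± 0.23) led them.

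Toll-like receptor pathway genes moved both ways, with 5 of 15 higher and 1 lower, or 6 higher and 3 lower when adjusted over the list alone (median 0.47). Camera called the list higher (adjusted p = 0.044; adjusted p = 0.35 with an estimated correlation), and this call was lost without control replicate 2 (adjusted p = 0.075) or LPS replicate 1 (0.065), after quantile normalization (0.13) and with a minimum mean of 50 (0.16, range 2.2e-04 to 0.16). Tlr3, a sensor of double-stranded RNA, rose by 3.62 ± 0.36, Tlr2, a sensor of bacterial lipoproteins, by 2.93 ± 0.36, and the adaptor Myd88 by 2.73 ± 0.23. Cd14, the co-receptor for LPS, went from 666 ± 83.5 to 3689 ± 460 CPM, 5.54-fold higher (adjusted p = 0.0026). Tlr4 itself had a log2 fold change of -0.43 ± 0.19 without a call in the fit without a block (adjusted p = 0.27). With the replicate number as a block, edgeR called Tlr4 lower (-0.43, adjusted p = 0.0085). Another 11 members, 10 of them with more than 1 accession, lay under the count minimum and were not tested. The kinase adaptor Tab2 (1.27, adjusted p = 0.023) and Tlr13, a sensor of bacterial ribosomal RNA and the 1 member that fell (-1.65, 0.0069), were chosen after their values were seen. Without LPS replicate 1 or LPS replicate 2 both lost their calls, at 1.10 and 1.42 for Tab2 (0.16 and 0.067, range 0.0011 to 0.16) and -1.59 and -1.71 for Tlr13 (0.073 and 0.055, range 5.9e-07 to 0.073). The call of Tab2 was also lost in limma without a trend (1.17, 0.16), after quantile normalization (0.81, 0.052) and with total-count scaling (0.83, 0.067). Of 13 immediate-early transcription factors, 5 rose, also when adjusted over the list alone. The list had a median of -0.23 but a mean of 0.48, and camera, whose direction was upward, did not call it (adjusted p = 0.079; adjusted p = 0.65 with an estimated correlation). It was called higher without control replicate 1 (0.018), without a filter (0.0018) and among genes with 1 accession (0.049, range 0.0018 to 0.58). Maff, Junb and Atf3 rose by 2.02 ± 0.23, 1.96 ± 0.20 and 1.86 ± 0.22. Ier3 rose by 1.88 ± 0.37, a call lost without LPS replicate 1 (1.76, adjusted p = 0.16) or LPS replicate 2 (1.99, 0.092, range 3.3e-04 to 0.16). Klf6, chosen after its values were seen, rose by 0.97 (adjusted p = 0.041), a call lost without control replicate 2 (0.83, 0.11), LPS replicate 1 (0.87, 0.28) or LPS replicate 2 (1.07, 0.15, range 0.0077 to 0.30), in limma-trend (0.88, 0.13), in limma without a trend (0.88, 0.30), after quantile normalization (0.37, 0.22) and with total-count scaling (0.55, 0.14). Without LPS replicate 1 or LPS replicate 2 the list held 3 calls.

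**Figure D1:**
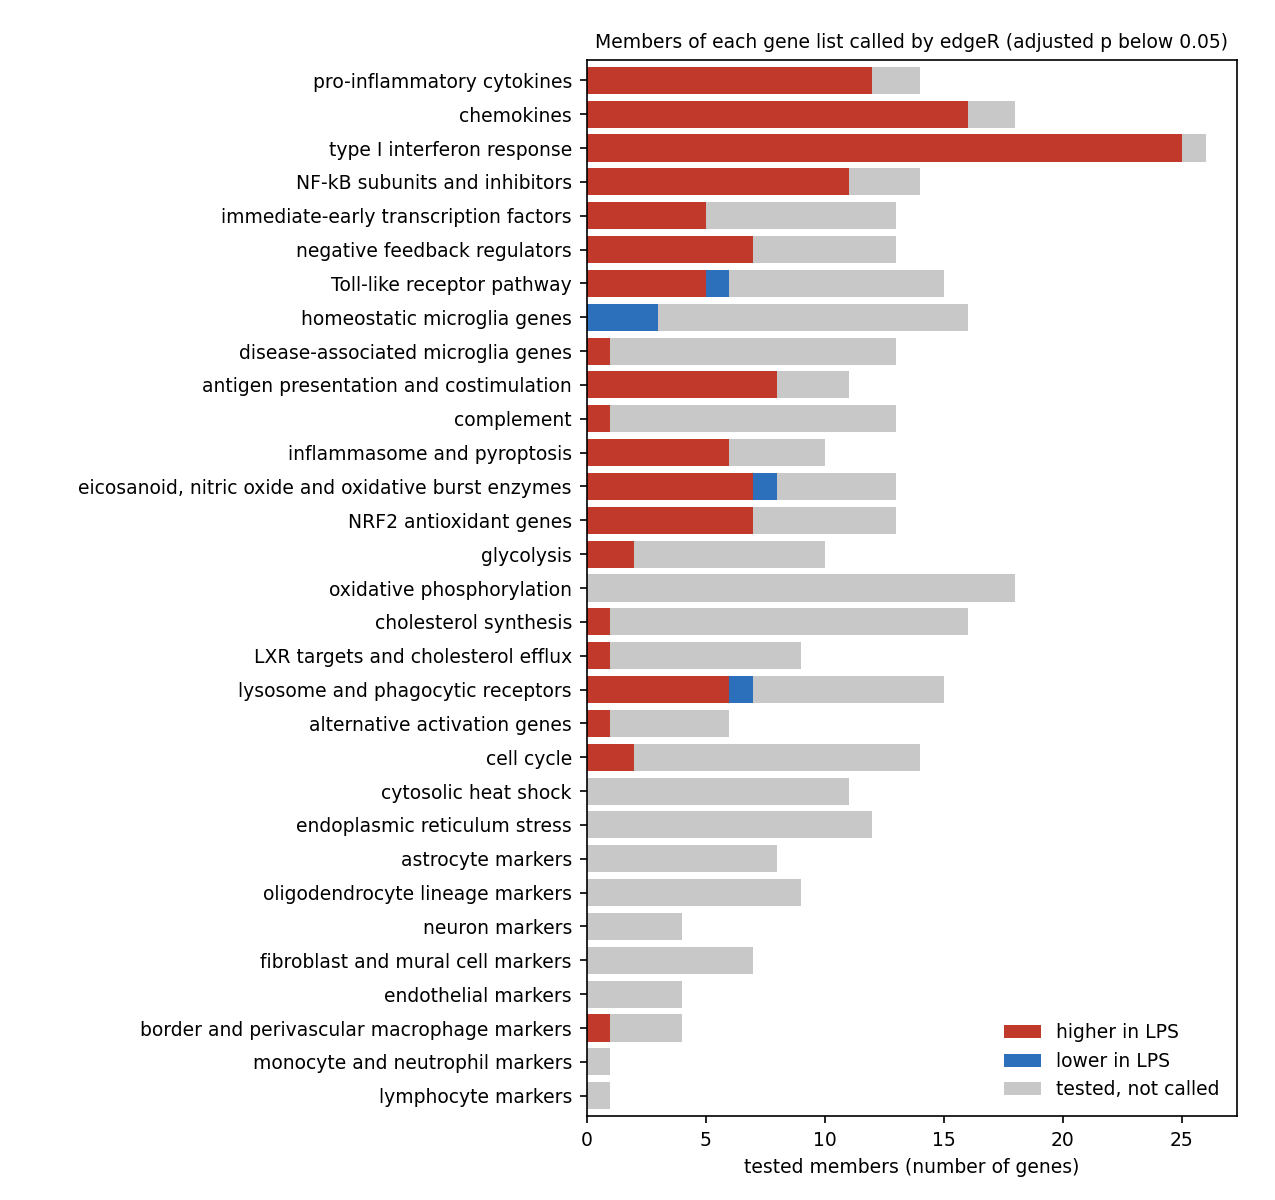
Number of tested genes (horizontal axis) in each gene list fixed before the data were examined, 1 stacked bar per list, split into genes called higher in LPS, called lower, and not called by edgeR. The type I interferon list has 25 of 26 genes called higher and the oxidative phosphorylation list 0 of 18.

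Enzymes of eicosanoid, nitric oxide and oxidative burst synthesis were higher for 7 of 13 genes and lower for 1, or 8 and 2 when adjusted over the list alone (median 2.17; camera adjusted p = 1.4e-12; adjusted p = 0.34 with an estimated correlation). Ptges, the terminal synthase of prostaglandin E2, rose by 7.34 ± 0.29. Nos2, the inducible nitric oxide synthase, went from 2.12 ± 1.12 to 136 ± 36.9 CPM, 61.4-fold higher (adjusted p = 0.0016; log2 5.94, or 6.62 without control replicate 2). Gch1, which makes the cofactor of nitric oxide synthase, rose by 4.33 ± 0.29. Ptgs2, the inducible cyclooxygenase, had 172 and 1263 counts in control and 10993 and 9910 in LPS and rose by 4.11 ± 0.80 (adjusted p = 0.036). Ptgs2 had values of 3.35 without control replicate 1 and 5.76 without control replicate 2, and its call was lost without LPS replicate 1 (4.04, adjusted p = 0.081), without LPS replicate 2 (4.18, 0.063) and after quantile normalization (3.71, 0.055, range 9.7e-10 to 0.081). Ptgs1, the constitutive cyclooxygenase and the member that fell (-1.62, adjusted p = 0.032), was chosen after its values were seen. The call of Ptgs1 was lost without control replicate 1 (-1.27, 0.072), LPS replicate 1 (-1.58, 0.20) or LPS replicate 2 (-1.66, 0.14, range 0.0027 to 0.20). In the inflammasome and pyroptosis list, 6 of 10 genes rose, or 6 with 1 lower when adjusted over the list alone (median 1.47; camera adjusted p = 4.7e-06; adjusted p = 0.30 with an estimated correlation). The sensor Nlrp3 rose by 6.01 ± 0.57 (6.68 without control replicate 1), the inflammatory caspases Casp4 and Casp1 by 4.57 ± 0.28 and 2.63 ± 0.24, and the DNA sensor Aim2 by 1.68 ± 0.20, a call lost in limma without a mean-variance trend (1.58, adjusted p = 0.058, range 2.5e-06 to 0.058).

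NRF2 antioxidant genes rose in 7 of 13 cases, and in 9 when adjusted over the list alone (median 1.51; camera adjusted p = 1.3e-05; adjusted p = 0.30 with an estimated correlation). The cystine transporter Slc7a11 rose by 3.16 ± 0.25, thioredoxin reductase Txnrd1, with 4 accessions and an uncertain level, by 3.13 ± 0.51, sulfiredoxin Srxn1 by 1.88 ± 0.25 and heme oxygenase Hmox1 by 1.78 ± 0.35. Without LPS replicate 1 the list held 2 calls, and those of Txnrd1 (2.86, adjusted p = 0.097, range 0.0029 to 0.097), Srxn1 (1.68, 0.056, range 6.1e-07 to 0.056) and Hmox1 (1.27, 0.13) were lost. That of Txnrd1 was also lost without control replicate 2 (adjusted p = 0.071; log2 ratio from counts 2.92, interval 1.30 to 5.25), and that of Hmox1 after quantile normalization (0.72, 0.18, range 1.5e-04 to 0.18) and in limma without a trend (1.64, 0.071). In glycolysis, 2 of 10 genes rose and 4 when adjusted over the list alone (median 0.69; camera adjusted p = 0.029; adjusted p = 0.34 with an estimated correlation). The list's call was lost without control replicate 2 (adjusted p = 0.096) or LPS replicate 1 (0.094), after quantile normalization (0.13), with a minimum mean of 50 (0.16, range 0.0046 to 0.16) and with total-count scaling (0.072). Of the list, 8 members lay under the count minimum, 7 of them with more than 1 accession, Gapdh and Ldha among these. Fry did not call the list (fry adjusted p = 0.061). The glucose transporter Slc2a1 rose by 2.2 ± 0.22 and phosphoglycerate kinase Pgk1 by 1.07 ± 0.18 (adjusted p = 0.023). The call of Pgk1 was lost without control replicate 1 (1.01, 0.053), LPS replicate 1 (1.14, 0.13) or LPS replicate 2 (0.99, 0.18), in limma-trend (0.98, 0.10), in limma without a trend (0.98, 0.27), after quantile normalization (0.19, 0.64, range 0.0019 to 0.64) and with total-count scaling (0.63, 0.15).

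Oxidative phosphorylation genes had 0 calls among 18 in edgeR, DESeq2 and limma-trend, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (median 0.21; camera adjusted p = 0.88; adjusted p = 0.95 with an estimated correlation). The ATP synthase subunits Atp5b and Atp5a1 had log2 fold changes of 0.31 (adjusted p = 0.40) and 0.06 (0.95), and -0.36 and -0.44 after quantile normalization. In cholesterol synthesis 1 of 16 genes rose, with 1 higher and 1 lower when adjusted over the list alone (median 0.04, mean -0.01; camera adjusted p = 0.93; adjusted p = 0.95 with an estimated correlation). With any 1 of the 4 libraries left out, 0 genes of the list were called higher by edgeR. Among LXR targets and cholesterol efflux genes 1 of 9 rose, with 1 higher and 1 lower when adjusted over the list alone (median -0.05, mean 0.57; camera adjusted p = 0.46, direction upward; adjusted p = 0.95 with an estimated correlation). It was Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol, at 6.16 ± 0.29. The number of genes of this list called lower was 1 without control replicate 2 or with a minimum mean of 50, and 2 after quantile normalization or with total-count scaling.

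Homeostatic microglia genes, a signature of surveying microglia, fell in 3 of 16 cases, also when adjusted over the list alone. Their median log2 fold change was -0.95 (-0.89 within the libraries numbered 1 and -0.57 within those numbered 2). Fry did not call the list (fry adjusted p = 0.23, direction downward). Camera called the list lower (adjusted p = 0.0017; adjusted p = 0.64 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.054, range 4.3e-06 to 0.054). Among the genes that fell were the TGF-beta receptor Tgfbr1 (-1.44 ± 0.18, adjusted p = 0.0080) and the secreted glycoprotein Olfml3 (-1.29 ± 0.22, 0.024). Without LPS replicate 1 or LPS replicate 2 all 3 calls were lost, with values of -1.41 and -1.48 for Tgfbr1 (adjusted p = 0.091 and 0.073, range 9.2e-06 to 0.091) and -1.19 and -1.41 for Olfml3 (0.22 and 0.12, range 0.0053 to 0.22). Without control replicate 2 the list held 5 calls. Olfml3 was also lost without control replicate 1 (-1.28, 0.050), and Tgfbr1 and Olfml3 in limma without a trend (0.063 and 0.093). The purinergic receptor P2ry12 (-1.29 ± 0.47, adjusted p = 0.19) and the surface protein Tmem119 (-1.19 ± 0.37, 0.13) were not called in this fit without a block. Their values were -1.03 and -1.41 within the libraries numbered 1 and -1.48 and -0.83 within those numbered 2. With the replicate number as a block, 12 genes of the list were called lower and 1 higher, and both these genes were among the 12. The fit without a block leaves differences between the numbers in its residual spread. A gene without a call there can be called with the block. The labels do not say what a number marks, so this block stays an alternative. The fractalkine receptor Cx3cr1 had 1245 and 281 counts in control and 584 and 211 in LPS (-1.0 ± 0.88, adjusted p = 0.61). Its value was 0.79 (adjusted p = 0.47) without control replicate 1 and -1.82 (0.033, range 0.033 to 0.91) without control replicate 2. Summed over the list, levels were 3733 and 2797 CPM in control replicates 1 and 2 and 2418 and 1822 CPM in the LPS libraries, while summed oligodendrocyte markers were 517 and 74.0 CPM in control and 537 and 67.4 CPM in LPS.

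Disease-associated microglia genes rose in 1 of 13 cases, also when adjusted over the list alone (median 0.00, mean -0.09; camera adjusted p = 0.88, direction downward; adjusted p = 0.95 with an estimated correlation), and camera called the list lower after quantile normalization (0.013, range 0.013 to 0.96). This was the cystatin Cst7 at 1.51 ± 0.31 (adjusted p = 0.044), lost without control replicate 2 (1.22, 0.079), LPS replicate 1 (1.24, 0.25, range 0.0044 to 0.25) or LPS replicate 2 (1.73, 0.076), and after quantile normalization (1.33, 0.056), total-count scaling (1.08, 0.062) or in limma without a trend (1.41, 0.090). The number of genes of this list called lower was 1 without control replicate 1, in DESeq2, in limma-trend and with total-count scaling, and 3 after quantile normalization, while without a filter 2 were called higher and 2 lower. The lipid receptor gene Trem2 had 0, 2, 1 and 0 counts over 2 accessions and was not tested. Of lysosome and phagocytic receptor genes, 6 of 15 rose and 1 fell, or 6 and 2 when adjusted over the list alone (median 0.30; camera adjusted p = 0.066; adjusted p = 0.35 with an estimated correlation). The list was called higher without control replicate 1 (0.040) or LPS replicate 2 (0.033), without a filter (0.0031, range 0.0031 to 0.93) and in the limma fits without quantile normalization (0.043 to 0.049). The scavenger receptor Marco rose by 4.77 ± 0.68 (5.76 without control replicate 2 and 4.03 without LPS replicate 2), the protease cathepsin C gene Ctsc by 2.23 ± 0.19 and the activating IgG receptors Fcgr4 and Fcgr1 by 2.02 ± 0.34 and 1.98 ± 0.22. The call of Fcgr4 was lost without LPS replicate 1 (2.12, adjusted p = 0.084) or LPS replicate 2 (1.91, 0.097, range 1.6e-04 to 0.097), with total-count scaling (1.56, 0.066) and in limma without a trend (1.98, 0.054). Fcgr3, another IgG receptor, fell by 1.62 (adjusted p = 0.0082) and was chosen after its values were seen; its call was lost without LPS replicate 1 (-1.63, 0.072, range 2.0e-06 to 0.072) or LPS replicate 2 (-1.62, 0.067) and in limma without a trend (-1.71, 0.052). Without either LPS library the list held 3 genes called higher. In complement, 1 of 13 genes rose, also when adjusted over the list alone (median -0.09, mean 0.29; camera adjusted p = 0.81, direction upward; adjusted p = 0.95 with an estimated correlation). It was the central component C3 at 3.59 ± 0.25. Among alternative activation genes 1 of 6 rose, also when adjusted over the list alone (median 0.28; camera adjusted p = 0.69; adjusted p = 0.86 with an estimated correlation). It was the transglutaminase Tgm2 at 2.56 ± 0.35.

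**Figure D2:**
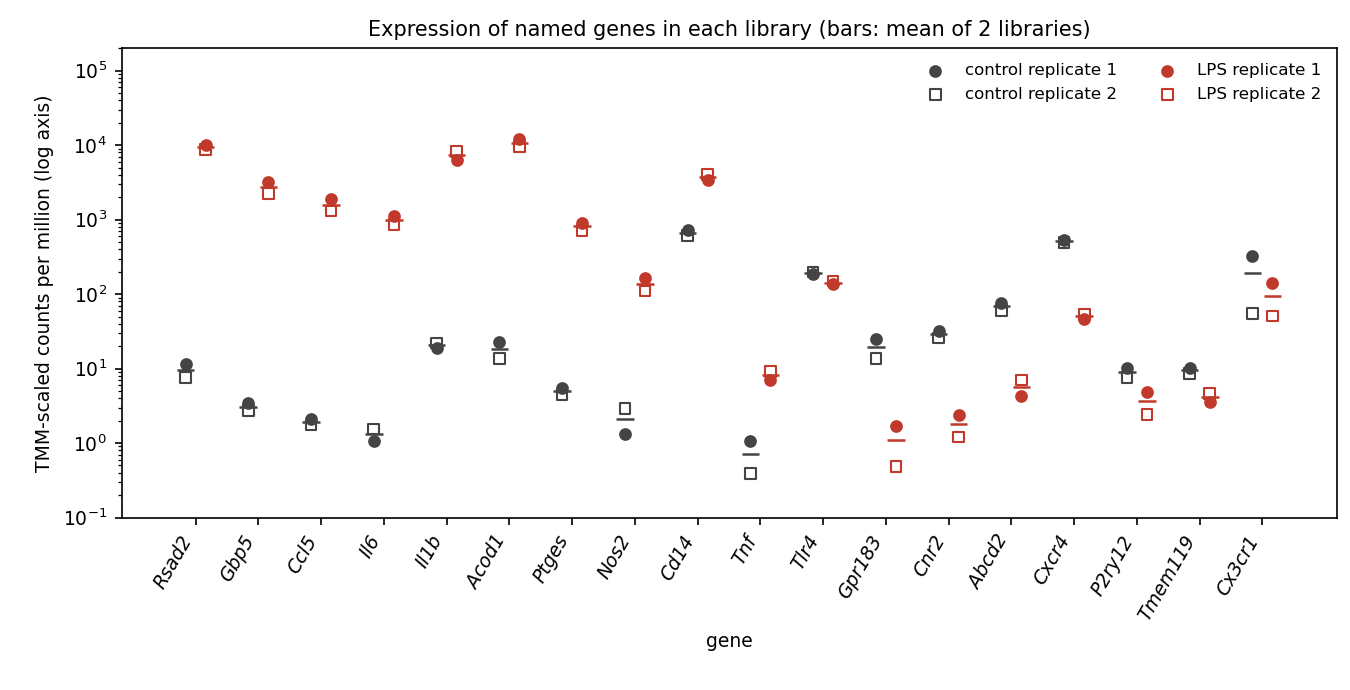
Levels of single genes as TMM-scaled CPM (log axis) for each control and LPS library, with lines at group means. Il6 lies near 1.30 CPM in control and 993 CPM in LPS, and Cxcr4 goes from 513 to 50.3 CPM.

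Gpr183 and Cnr2, the first by size of the 10 genes with the largest decreases, encode receptors. Gpr183 (chromosome 14, 121952331 to 121965193), a receptor of oxysterols derived from the product of Ch25h, went from 19.4 ± 8.20 to 1.08 ± 0.849 CPM, 17.3-fold lower (adjusted p = 0.017). Its log2 fold change was -4.11. Without LPS replicate 1 its log2 ratio from counts was -5.26 (interval -8.31 to -3.38), and its call was lost without LPS replicate 2 (-3.49, adjusted p = 0.055, range 2.7e-06 to 0.055). Cnr2 (chromosome 4, 135895189 to 135920219), a cannabinoid receptor of immune cells, went from 28.9 ± 4.44 to 1.81 ± 0.846 CPM (log2 fold change -3.98 ± 0.41, adjusted p = 0.0046). Abcd2, a peroxisomal transporter of fatty acids, changed by -3.58 ± 0.34, Dkk2, a secreted modulator of Wnt signalling, by -3.40 ± 0.28, the sulfotransferase gene Chst10 by -3.41 ± 0.30 and Cxcr4 (chromosome 1, 128588199 to 128592299) by -3.35 ± 0.21. Rassf3 (-3.63 ± 0.39), Tmem154 (-3.38 ± 0.39), N4bp2l1 (-3.55 ± 0.62) and the transcription factor gene Lyl1 (-3.35 ± 0.46) completed this group. The call of N4bp2l1 was lost without LPS replicate 1 (-2.85, adjusted p = 0.069, range 6.0e-05 to 0.069), its log2 ratio from counts was -5.01 (interval -8.07 to -3.13) without LPS replicate 2, and the call of Lyl1 was lost without LPS replicate 2 (-3.07, 0.056, range 7.4e-07 to 0.056).

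Cell cycle genes rose in 2 of 14 cases, also when adjusted over the list alone (median -0.20, mean 0.02; camera adjusted p = 0.93, direction downward; adjusted p = 0.95 with an estimated correlation). The proliferation marker Mki67 went from 8.32 ± 1.35 to 61.1 ± 13.6 CPM (2.88 ± 0.30, adjusted p = 0.0046). The replication clamp gene Pcna rose by 0.89 ± 0.19 (adjusted p = 0.046), a call lost without control replicate 1 (0.89, 0.095), control replicate 2 (0.85, 0.11), LPS replicate 1 (0.77, 0.32) or LPS replicate 2 (1.01, 0.16, range 0.014 to 0.38), in limma, after quantile normalization and with total-count scaling. Cytosolic heat shock genes had 0 calls among 11 in edgeR, DESeq2 and limma-trend, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (median -0.16, mean -0.01; camera adjusted p = 0.93; adjusted p = 0.95 with an estimated correlation). The chaperones Hspa8 and Hsp90ab1 had values of 0.30 (adjusted p = 0.61) and 0.35 (0.46), and of -0.73 and -0.63 after quantile normalization. Endoplasmic reticulum stress genes had 0 calls among 12 in edgeR, DESeq2 and limma-trend and 0 when adjusted over the list alone, while 3 were lower at an unadjusted p under 0.05 (median -0.28; camera adjusted p = 0.18; adjusted p = 0.65 with an estimated correlation). Camera called this list lower after quantile normalization (0.013, range 0.013 to 0.43). Its most abundant tested members were Pdia6 at 0.19 (adjusted p = 0.69) and Hsp90b1 at -0.16 (0.85). Hspa5, Ddit3, Atf4 and Xbp1, 4 members with more than 1 accession, had mean counts of 0, 4.5, 0 and 0 and were not tested. Kdm6b, a histone demethylase gene, had a log2 fold change of 0.86 ± 0.31 without a call in the fit without a block (adjusted p = 0.19). With the replicate number as a block, edgeR called Kdm6b higher (0.87, adjusted p = 0.016).

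Markers of other cell types that mixed glial cultures can hold were present in all 4 libraries. In the fit without a block, edgeR called 1 of 38 tested markers. Summed astrocyte markers were 121 and 323 CPM in control and 136 and 452 CPM in LPS replicates 1 and 2, and summed fibroblast and mural cell markers were 89.3 and 326 CPM in control and 105 and 354 CPM in LPS. The myelin gene Mag had 680 and 17 counts in control and 854 and 15 in LPS (log2 fold change 0.20, adjusted p = 0.97), and the astrocyte water channel gene Aqp4 had 34 and 601 counts in control and 60 and 870 in LPS (0.83, 0.82). Neither the 8 astrocyte (camera adjusted p = 0.93), 9 oligodendrocyte (0.88), 4 neuron (0.93), 7 fibroblast and mural (0.78) nor 4 endothelial markers (0.93) held a call in edgeR, DESeq2 or limma-trend, when adjusted over each list alone, or at an unadjusted p under 0.05. The adjusted p was 0.95 with an estimated correlation for each of these lists. These fits had little power for markers that differed between the numbers, with standard errors of 1.91 for Mag, 1.42 for Aqp4 and 0.94 for Acta2. With the replicate number as a block, edgeR called 1 astrocyte marker (Aqp4, 0.81, adjusted p = 3.5e-04) and 2 fibroblast and mural markers higher. Col3a1 (0.77, 0.011) was among these 2. It also called 1 oligodendrocyte marker lower, and 0 neuron or endothelial markers. Ugt8a (0.13, adjusted p = 0.98), Gfap (0.38, 0.84, over 2 accessions), Tubb3 (-0.01, 0.99), Stmn2 (0.15, 0.96), Acta2 (0.02, 0.99), Col3a1 (0.77, 0.34), Vwf (-0.13, 0.89) and Cdh5 (0.30, 0.86) were among the most abundant tested members of these lists. They held no call in the edgeR fit without a block, which gave these values. Without control replicate 2, the remaining control library held 517 CPM of oligodendrocyte markers, against 537 and 67.4 CPM in LPS. Treatment and number are then mixed, and the value of Mag, 0.20 in all libraries, was -0.84. Of 4 border and perivascular macrophage markers 1 rose, also when adjusted over the list alone (camera adjusted p = 0.34; adjusted p = 0.64 with an estimated correlation). It was the lectin receptor Clec12a at 1.70 ± 0.21 (adjusted p = 0.0078), a call lost without LPS replicate 1 (1.65, 0.055) and in limma without a trend (1.61, 0.058, range 2.7e-06 to 0.058). Summed border macrophage markers were 71.8 and 61.0 CPM in control and 172 and 145 CPM in LPS, of which Clec12a alone made up 36.5 and 41.1 CPM in control and 131 and 122 CPM in LPS. The other 3 tested members were not called. The monocyte and neutrophil list had 1 tested member, S100a8 (0.87, adjusted p = 0.21), and the lymphocyte list had Cd3d (-0.96, 0.35), so neither was tested as a set. With 1 member, the p adjusted over the list alone is the unadjusted p, 0.040 for S100a8 and 0.10 for Cd3d.

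**Figure D3:**
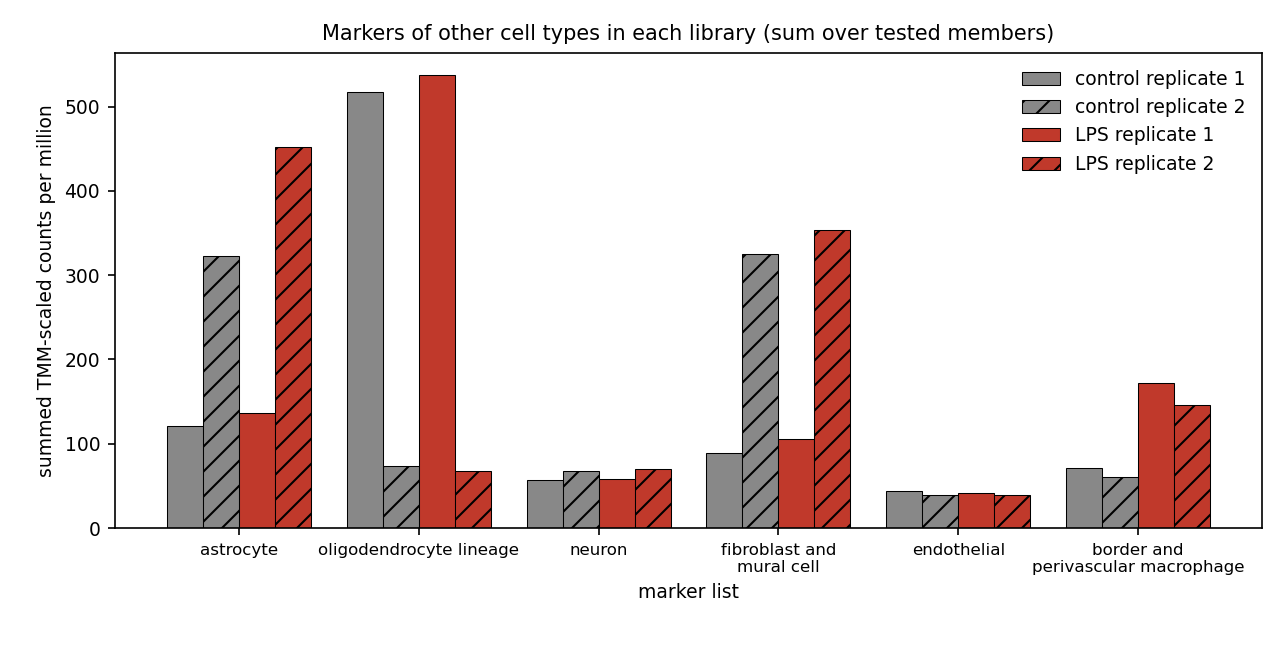
Summed levels of markers of other cell types as TMM-scaled CPM for each library. Oligodendrocyte markers reach 517 and 537 CPM in the libraries numbered 1 and 74.0 and 67.4 CPM in those numbered 2, while astrocyte markers are higher in those numbered 2.

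Camera with its preset correlation called 12 of the 29 lists it could test, 11 higher and 1 lower. With an estimated correlation 0 of these 12 were called (lowest adjusted p 0.15), although 4 of the 12 had an unadjusted p under 0.05. That test rests on the few residual degrees of freedom of 4 libraries, so it could hardly reach a call over 29 lists. Most called lists had an estimated correlation above the preset of 0.01, from 0.10 for NRF2 genes to 0.54 for eicosanoid enzymes. It was 0.51 for chemokines, 0.37 for homeostatic microglia genes and 0.35 for type I interferon genes. The preset p-values do not allow for correlation of this size. Exceptions were Toll-like receptor genes (0.013), glycolysis (-0.095) and pro-inflammatory cytokines. For pro-inflammatory cytokines the estimated correlation was -0.030, yet the camera p went from 1.2e-39 to 0.0050. Camera with an estimated correlation therefore cannot tell whether correlation between genes accounts for the preset calls. The self-contained test fry, which asks only whether a list's genes move on balance in 1 direction, called 10 of the 12. It did not call glycolysis (fry adjusted p = 0.061) or homeostatic microglia genes (0.23), the 1 list that camera called lower.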

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

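Total-count scaling, limma-trend on log2(count + 1), and the runs on single-accession genes, per accession and without the most abundant accessions were chosen after the data were seen. Apart from quantile normalization, the limma fits did not correct for depth, so they change more than the test. Of 74 called named genes, 54 kept direction and call in every setting and 0 changed sign. All 796 called genes kept their sign in each setting that tested them, except B2m under quantile normalization. Counts of calls stayed within 1.5 times of the reported ones except as follows. Quantile normalization gave 322 lower genes (282 at least 2-fold). Total-count scaling gave 489 lower genes (476 at least 2-fold) and moved the median log2 fold change of all genes to -0.48. Genes called at least 2-fold higher held 3.72% of counts in control and 21.3% in LPS. With the replicate number as a block, 1676 genes were higher and 1258 lower (553 at least 2-fold lower), among them all 796. Deviations of same-numbered libraries correlated across genes (Pearson 0.656, Spearman 0.579, genes not being independent), but the labels do not say what a number marks. For the number itself, with treatment as the other term, 785 genes were called higher and 1276 lower in the libraries numbered 2. The common coefficient of variation was 0.097 with the block and 0.283 without it. The block added calls for lysosome and phagocytic receptors (adjusted p = 0.011) and for 9 named genes (Tlr4, P2ry12, Tmem119, Cx3cr1, Kdm6b, Hsp90ab1, Aqp4, Col3a1 and S100a8), and for Ifi44. Camera with an estimated correlation called 0 lists at an adjusted p under 0.05 and 4 of the 12 at an unadjusted one, where fry called 10. Few residual degrees of freedom limited that camera test whatever the correlation. With 1 library left out, which leaves a lone sample assumed to vary like the other group, higher genes numbered 335 to 629, lower genes 33 to 260, at least 2-fold higher 335 to 629, at least 2-fold lower 33 to 259, and lists 10 to 13. The lowest came without LPS replicate 1 and the highest count of lower genes without control replicate 2. Fewer samples reduce power by construction; for the other shifts the cause was not tested.

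Signs that reversed belong to genes without a call, B2m apart. Atp5a1 and Acta2 went to -0.051 and -0.074 in limma-trend, with a pseudocount of 0.5 and without a trend, to -0.051 and -0.075 with a pseudocount of 8, and to -0.044 and -0.085 with a minimum mean of 50. Quantile normalization gave Atp5b -0.36, Atp5a1 -0.44, Hspa8 -0.73, Hsp90ab1 -0.63, Pdia6 -0.32, Acta2 -0.36 and B2m -0.19. Total-count scaling gave Atp5b -0.12, Atp5a1 -0.38, Hspa8 -0.14, Hsp90ab1 -0.065, Pdia6 -0.24, Gfap -0.074, Mag -0.17, Ugt8a -0.24, Stmn2 -0.32, Acta2 -0.45 and Cdh5 -0.18, all above the shifted median. Tubb3 went to 0.094 without a filter, 5.4e-04 with filterByExpr, 0.0031 with DESeq-type factors and 0.0035 in DESeq2. With 1 library left out, values spanned -1.91 to 0.79 for Cx3cr1, -0.32 to 0.36 for Atp5a1, -2.13 to 3.63 for Aqp4, -0.82 to 1.32 for Gfap, -0.17 to 0.12 for Tubb3, -1.58 to 1.83 for Stmn2, -1.56 to 1.58 for Acta2, -0.46 to 0.22 for Vwf, -0.33 to 1.56 for Cdh5, -4.64 to 4.94 for Mag, -3.05 to 3.41 for Ugt8a and -0.64 to 0.20 for Hsp90b1. Leaving 1 library out unbalances the numbers between groups. Mag stood at 180 and 205 CPM in the libraries numbered 1 and 3.29 and 3.62 CPM in those numbered 2. Its range follows from which library was missing. For the other reversals the cause was not tested. Depth limits genes with few counts, such as Il10.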

Other observations

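The tests on symbol families and on libraries of the same number were chosen after the result was seen; those on genes with more than 1 accession were chosen after their low counts were seen, but before the values of the tests were. Families of genes with a shared symbol stem and at least 8 tested members were searched for calls (139 families, 278 one-sided Fisher's exact tests). In the Ifi family, which includes the interferon-induced nucleic acid sensors of chromosome 1, 8 of 11 genes were called higher (adjusted p = 6.2e-06), among them Ifi205 (log2 fold change 6.78), Ifi209 (6.72), Ifi204 (5.51) and Ifi211 (4.72). These paralogs are neighbours and can share reads, so the split among them is uncertain. Of the Parp family, enzymes that transfer ADP-ribose, 5 of 9 were called higher (adjusted p = 0.0083), with Parp14 at 5.47, Parp12 at 4.01 and Parp9 at 3.99. Of the Trim family of ubiquitin ligases, 7 of 24 were called higher (adjusted p = 0.036), with Trim30a at 4.33, Trim56 at 3.04 and Trim25 at 2.84, while the median over all 24 was -0.10. Trim30a and Trim30d, and Trim34a and Trim34b, were among the 7. Fisher's test treats genes as independent, which members of a family need not be, so these p-values may be too small. Ifi35 (among the 8), Ifi44 and Trim30a are also members of the type I interferon list. The call of Trim56 was lost without LPS replicate 1 (2.71, adjusted p = 0.094, range 7.6e-07 to 0.094), and its value was 4.03 without control replicate 2; that of Ifi205 was 6.03 without control replicate 1, and its log2 ratio from counts was 9.15 (interval 7.30 to 12.20) without control replicate 2. The Ccl (9 of 11, adjusted p = 2.8e-07) and Cxcl families (7 of 9, 1.5e-05) repeat the chemokine list. For genes called lower, no family passed; the nearest was Gpr, with 3 of 24 (adjusted p = 0.30).

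Genes with more than 1 accession had low counts. Genes with 1 accession had a median mean count of 7.5 and 46.8% of them reached a mean of 10, against medians of 0.5 and 0.75 and shares of 12.8% and 10.2% for genes with 2 and with 3 or more. Lower expression of such genes in these cells is argued against by ribosomal protein genes, needed in similar amounts: 64 with 1 accession had a median of 1264 counts and 11 with more had a median of 0, a ratio of 0. Reads shared between the accessions of a gene may not have been counted, since across 3427 genes the count rose with the exonic bases held by 1 accession alone (Spearman rho = 0.5415, across genes, which are not independent). This hypothesis would leave genes such as Trem2 and Gapdh unmeasured here rather than low, and no biological explanation was tested beyond expression level.

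Libraries of the same number shared levels of markers of other cell types in both groups. In a fit with treatment as the other term, oligodendrocyte markers were lower in the libraries numbered 2 (9 of 9 called, median log2 difference -2.99, camera adjusted p = 7.7e-35), and astrocyte (3.8e-05) and fibroblast and mural markers (1.5e-04) were higher. Lists beyond other cell types differed too: homeostatic microglia genes (0.0028), chemokines, NF-kB and eicosanoid genes (0.024 each), and antigen presentation and LXR genes (0.025 each) were lower in number 2 and cytosolic heat shock genes higher (0.0020). The adjusted p was 0.70 with an estimated correlation for each of these lists. Mag stood at 180 and 205 CPM in the libraries numbered 1 and 3.29 and 3.62 in those numbered 2, and Acta2 at 54.3 and 54.4 against 266 and 272 CPM. Library size or scaling is argued against, as scaling moves all genes of a library alike, while the lists moved both ways. At least 96.32% of the Mag difference was left by total-count and DESeq-type scaling. Mag was picked for its large difference, so this adds little. A lower share of microglia RNA with all other cell types alike is also argued against, since the lists moved both ways, with 1 list in the less frequent direction. Different amounts of RNA of other cell types in the libraries numbered 1 and 2 stay open as an untested explanation, since the 3 lists of other cell types past the threshold only restate the pattern; no sort that would remove such cells is described, 0 members of the lists of other cell types are in another list, and S100b, an astrocyte list member, moved with the oligodendrocyte markers (37.3 and 39.5 against 2.71 and 2.66 CPM).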
